A study of Schizosaccharomyces pombe with 4 samples.

How the data were processed

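Chromatin immunoprecipitation with sequencing was done on fission yeast of 2 genotypes, wild type and a strain with abp1 deleted. Per the labels' protocols, cells growing exponentially in YES, a rich medium, were fixed with 1% formaldehyde for 15 min and quenched with 125 mM glycine. Chromatin was sheared to fragments of 250 to 400 bp, and polymerase II was precipitated with an antibody against phosphorylated serine 5. Libraries were made with a kit sold for RNA, per the labels' protocols. The labels give 4 samples: an input and a ChIP for each genotype. Groups were taken from the source names. The mutant ChIP is spelled with its letters in another order than its input there, and its genotype label gives the same deletion.

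Each ChIP sample has 1 interval list, and the input samples were not analysed here. Alignment used Bowtie 0.12.5, per the submitters' processing notes. The peak caller, the genome build, any scaling for depth, the use of the inputs and the treatment of reads with several matches are not given in the sources used here. The deposited lists have 4 columns with no header: chromosome, start, end and a whole number. That number is the authors' score for each interval. Its unit is not stated, the lowest value is 200 in both lists, and its values look like the highest read depth within a run of bases at or above 200. The score was used to describe, rank or filter intervals within 1 list. Whether the 2 lists were scaled alike is unknown, so no explanation was excluded by setting a score of 1 list against the other. Covered length rests on the same lowest score, so it also depends on depth and scaling. Depth per sample is unknown, so no limit for genes without an interval was computed.

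Coordinates were compared with the reference given for this work, the fission yeast assembly ASM294v3 and its RefSeq annotation. No interval ended past a chromosome. As deposited, 89.6% of wild-type and 90.4% of abp1Δ covered bases lay in protein-coding genes, against at most 78.7% and 79.8% when the lists were moved by 1000 to 10000 bp, so the deposited coordinates were used with this annotation. Positions are 1-based on it. The annotation gives the symbol abp1 to another gene, and the deleted gene was taken by its systematic name, SPBC1105.04c. Intervals did not overlap each other within a list, 28.5% of wild-type and 27.0% of abp1Δ intervals were 1 bp wide, and the smallest gap between neighbours was 1 bp.

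The samples and the main tests, gene lists and alternatives were fixed before the data were examined, and others, named as such below, were chosen afterwards. With 1 list per genotype no p-value was computed. Overlap of intervals by at least 1 bp counted as shared, with 95% Wilson intervals and 1000 random placements that keep widths and chromosomes. A gene was occupied at its start where an interval met the window from 250 bp before to 250 bp after the annotated start. It was occupied in the body where an interval met any base between start and end. Each interval was classed by its midpoint, in the order start window, gene body, 250 bp past a gene end, intergenic. The files give no summit, so classing by summit was not run. For gene lists of protein-coding genes, counts were set beside 10000 random lists with the same number of genes from each of 10 length classes. These draws describe the 2 libraries and are not tests. Repeats were described by the share of 36-mers and 50-mers found once in the genome, counted on both strands. A gene with under 10% of its 50-mers repeated was called single-copy.

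The planned lists were the CENP-B family, glycolysis and fermentation, histones, chaperones and heat shock, core stress response, translation factors, plasma membrane and cell wall, meiotic genes, mating and sexual differentiation, iron, phosphate, auxotrophy markers, RNA polymerase II subunits, Tf2 elements, ribosomal protein genes, wtf genes, rRNA, tRNA, snRNA, snoRNA and other non-coding RNA genes, long terminal repeats, Tf2 neighbours and subtelomeric genes. A list of centromeric features was planned, but the annotation used here names none. Lists for sulfur assimilation and for nitrogen and vacuolar protease genes, and the stretch of chromosome III, were chosen after seeing the data. So were the position profile along genes, the scores of regions in 1 list alone, the ranks of regions in both lists by score, and the comparison of covered bp per list.

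Genes to be named were fixed by a rule: the deleted gene, cbh1 and cbh2, all Tf2 elements and rRNA genes; then the 10 protein-coding genes with the highest score in the start window for each genotype alone; then up to 4 members of each list, those that differ between genotypes first; then the 5 highest intervals of each list. Other genes are named as members of a list with their covered length, and genes beyond these are said to be chosen afterwards.

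Alternatives were the upper 50% of each list by score, lists cut to equal length, other overlap rules, start windows of 100 and 500 bp, the gene body, a guard distance of 1 kb, merged gaps, and repeats with 500 bp added or covered over 50%. Added after seeing the data were merged gaps for overlap and classes, protein-coding genes alone for classes, and single-copy genes alone and the chromosome III stretch left out for occupied genes. The computations ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. They were tested on simulated lists: of 150 genes given an interval in both lists, 60 in wild type alone and 40 in abp1Δ alone, among 5113 protein-coding genes, all were recovered, with 0 others called. All 150 overlapping intervals were found in each simulated list.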

Results

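The study examined RNA polymerase II in the fission yeast Schizosaccharomyces pombe, in wild-type cells and in cells lacking Abp1, a homolog of the human centromere protein CENP-B. Polymerase phosphorylated at serine 5 of its C-terminal repeats (Ser5P), the form found from initiation into early elongation, was immunoprecipitated from cross-linked cells in exponential growth in rich medium, and the recovered DNA was sequenced. The labels list 4 samples, a ChIP and an input for each genotype. The 2 ChIP samples each carry 1 list of intervals with a score, and the inputs were not analysed here. With 1 list per genotype there is no replicate, so the values below describe these 2 lists and no test between genotypes was made. Read depth is unknown, and every deposited score was 200 or higher, so a gene without an interval may still carry polymerase below that level. Covered length is counted above the same level and depends on depth and scaling too. A difference in covered length between the lists, here and below, therefore need not be a difference in polymerase.

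The wild-type list held 3242 intervals and the abp1Δ list 2851. Together they covered 227413 bp in wild type and 249934 bp in abp1Δ, or 1.81% and 1.99% of the 3 chromosomes. The extra covered length of the mutant list lay mainly on chromosome III, where 39335 bp were covered in wild type and 52175 bp in abp1Δ. On chromosome I the values were 115273 and 121864 bp, and on chromosome II 72805 and 75895 bp. The highest deposited score of both lists fell on tef101, tef102 and tef103, the near-identical genes for translation elongation factor 1 alpha, with 2503 in wild type and 4092 in abp1Δ at each of the 3 copies. Their shared sequence means that these scores cannot be assigned to 1 copy and may count the reads of all 3. The cell wall protein gene pfl2 and its neighbour SPAPB18E9.05c came next, with 2250 in wild type and 2995 in abp1Δ. The fifth place went to SPAC27E2.11c in wild type, at 1996, and to the polyubiquitin gene ubi4 in abp1Δ, at 2642. The median interval was 4 bp wide in both lists, since runs of covered bases were broken into short pieces. Merging pieces up to 100 bp apart left 477 regions in wild type, with a median of 346 bp, and 442 in abp1Δ, with a median of 388 bp.

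How far the lists marked the same places was asked next. Of the wild-type intervals, 1812 of 3242 overlapped an abp1Δ interval by at least 1 bp, a share of 55.9% (95% Wilson interval 54.2 to 57.6%). Of the abp1Δ intervals, 1220 of 2851 overlapped a wild-type one, or 42.8% (41.0 to 44.6%). Random placement of the same intervals within their chromosomes gave means of 2.28% and 2.18%, and at most 3.18% and 3.09% in 1000 placements. Counted in bases, 186717 bp were shared, which is 82.1% of the wild-type and 74.7% of the abp1Δ length. Among merged regions, 348 of 477 in wild type (73.0%) and 324 of 442 in abp1Δ (73.3%) met a region of the other list. Regions found in 1 list alone mostly lay just above the lowest score: their median score was 216 in wild type and 222 in abp1Δ, against 348 and 377 for shared regions. The Wilson intervals cover counting error only, and neighbouring intervals are not independent.

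Few Ser5P intervals lay at annotated gene starts, and most lay farther inside genes. Of the 5113 protein-coding genes, 15 had an interval 150 bp before the start in wild type and 200 bp before it in abp1Δ, the lowest points of both profiles. The most genes were covered 600 bp past the start, 200 in wild type and 190 in abp1Δ. Farther past the start the mutant list had the higher counts: at 1350 bp 112 genes had an interval in wild type and 139 in abp1Δ. Positions were not limited to the gene, so at this distance they lie beyond the end of shorter genes. These counts therefore do not show deeper coverage within genes. When each interval was classed by its midpoint against protein-coding genes alone, 77.1% of wild-type and 80.5% of abp1Δ intervals lay in a gene body, 389 of 3242 and 290 of 2851 intervals in a start window of 250 bp each side, and 5.40% and 4.07% in intergenic sequence. Random placement put 65.4% in gene bodies, 19.3% in start windows and 12.5% in intergenic sequence. With all annotated genes, which include 7133 long non-coding RNA genes and leave little sequence free, start windows took 37.9% (36.3 to 39.6%) of wild-type and 34.8% (33.0 to 36.5%) of abp1Δ intervals. Gene bodies then took 59.8% (58.1 to 61.5%) and 63.2% (61.4 to 64.9%), and intergenic sequence 0.46% (0.28 to 0.76%) and 0.60% (0.37 to 0.95%). Random placement of the wild-type intervals put 42.4% in these start windows, 53.4% in gene bodies and 2.1% in intergenic sequence, with similar means for abp1Δ. Start windows thus took fewer intervals than random placement gave in both lists. The order of these classes depends on the window: with 500 bp each side, start windows took 66.0% and 64.2% and gene bodies 33.4% and 34.9%.

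**Figure D1:**
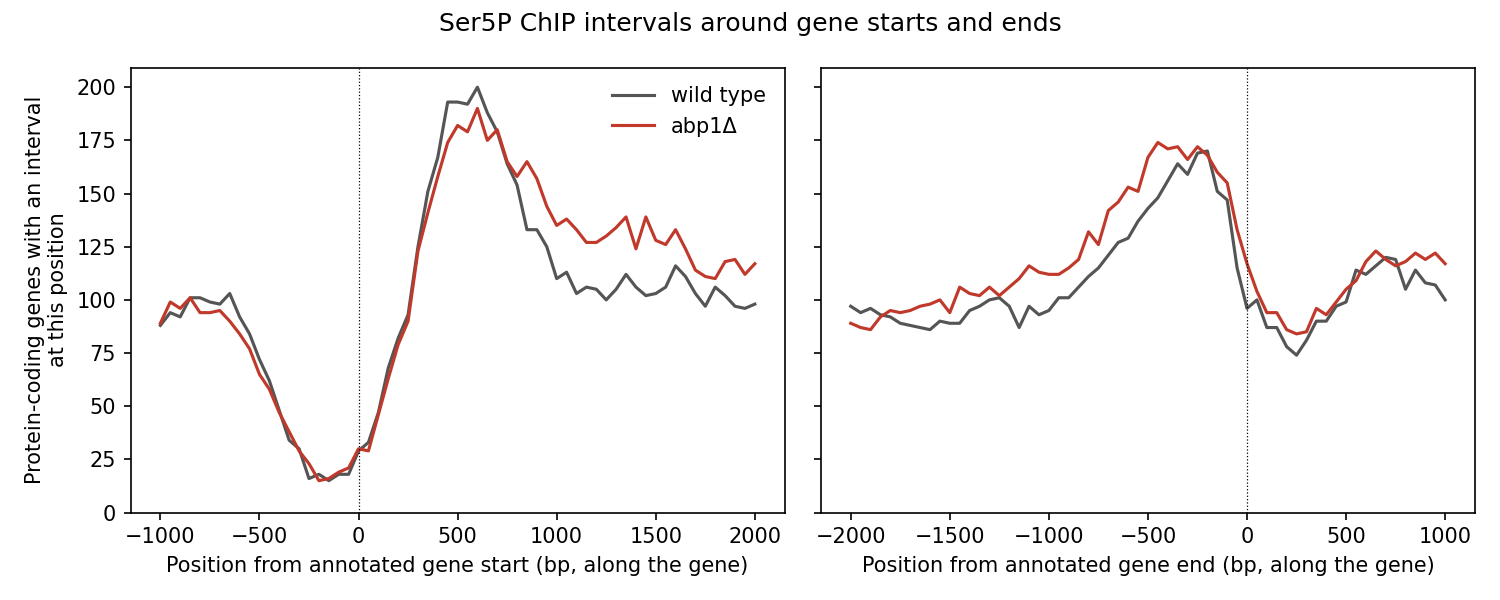
Number of protein-coding genes with an interval at each position from the annotated gene start (left) or gene end (right), in steps of 50 bp, for the wild-type (grey) and abp1Δ (red) lists. Both lines are lowest just before the start and highest near 600 bp past it, at 200 genes in wild type and 190 in abp1Δ.

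The series asks where Ser5P polymerase changes without Abp1, so each gene was called occupied where an interval met its start window. The deleted gene was looked at first. Its locus, SPBC1105.04c, carries the symbol cbp1 in the annotation used here (chromosome II, 3510427 to 3512370, minus strand), because abp1 now names another gene. It had no interval in either list, nor did its relatives cbh1 and cbh2, so the genotype labels were not checked by it. In wild type 144 protein-coding genes were occupied and in abp1Δ 141. The lists shared 114 of them, 30 were occupied in wild type alone and 27 in abp1Δ alone. Counting any interval from gene start to gene end gave 367 and 364 genes, of which 319 were shared, 48 were in wild type alone and 45 in abp1Δ alone. Only 7 of the 30 wild-type genes and 4 of the 27 abp1Δ genes had no interval of the other list within 1 kb, and 4 of those 7 are near-identical copies, the SPBPB10D8 genes, that count as 1 observation.

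Among genes occupied at the start in abp1Δ alone, the 10 with the highest scores mostly had intervals farther inside the gene in wild type too. They include rpl1202 and rpl6, which encode ribosomal proteins, with 366 and 462 covered bp in wild type and 614 and 737 in abp1Δ. The peroxiredoxin gene tpx1 had 33 covered bp in wild type and 561 in abp1Δ. The genes asl1 and byr3 had 1749 and 591 covered bp in wild type and 1806 and 808 in abp1Δ. The windows of SPAC1071.09c and jmj4 reached an interval of a neighbour, the proton pump gene pma1 and rpl6. In its body SPAC1071.09c had 115 covered bp in wild type and none in abp1Δ, and jmj4 had none in either list. Intervals anywhere in the gene were limited to abp1Δ for scw1, which encodes an RNA-binding protein and had 1420 covered bp, and for the adjacent SPCC417.16 and SPCC417.15, with 493 and 92 covered bp.

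Among genes occupied at the start in wild type alone, the same held for pfl2, the aldehyde dehydrogenase gene atd1, the glucanosyltransferase gene gas1, the chaperone gene bip1, the histone H3 gene hht3 and rpl2101. Their covered length was 4332 and 4051 bp (wild type and abp1Δ) for pfl2, 2328 and 2066 bp for atd1, 1881 and 1905 bp for gas1, 2387 and 2258 bp for bip1, 527 and 404 bp for hht3, and 299 and 252 bp for rpl2101. The exception was a cluster of 4 transporter genes near the left end of chromosome II, SPBPB10D8.04c, SPBPB10D8.05c, SPBPB10D8.06c and SPBPB10D8.07c (91376 to 101140). Each had 761 covered bp and a score of 440 in wild type and no interval in abp1Δ. At least 81.9% of the 50-mers in each gene occur more than once in the genome, so most reads of these copies cannot be assigned to 1 of them.

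Chosen after their values were seen, the longest gene-body coverage limited to wild type also included the drug efflux transporter gene bfr1 with 1286 bp, ecl2 with 998 bp and the hexokinase gene hxk2 with 692 bp. On the mutant side were cpy1, which encodes vacuolar carboxypeptidase Y, with 1384 bp and a score of 1828, SPAC27D7.11c with 1125 bp, the ammonium transporter gene amt1 with 905 bp and the vacuolar protease gene isp6 with 860 bp.

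Planned lists of glycolytic, translation, cell surface and chaperone genes had many occupied members, mostly the same ones in both genotypes. Start windows were occupied in 9 of 17 glycolysis and fermentation genes in each list, and gene bodies in 12 of 17 in each. The glycolytic genes tdh1, pgk1 and fba1 were covered over their whole length in both lists, and pyk1 over 90.7% in wild type and 92.1% in abp1Δ. The exceptions were hxk2, with an interval in wild type alone, and pgi1, with 98 bp in abp1Δ alone. Of 11 translation factor genes 8 were occupied at the start and 10 in the body in each list. Of these 10, 8 had more covered bp in abp1Δ and 1 had fewer, with 14544 bp in wild type and 15661 in abp1Δ in all. Some were nearly level, such as tif1 with 1278 bp in wild type and 1281 in abp1Δ, tif51 with 966 and 978 and tef103 with 1519 in both. The largest differences were at tef3, with 2909 and 3199, and tef5, with 107 and 593. Random draws of 10 protein-coding genes with an interval in either list had a mean of 5.43 with more covered bp in abp1Δ. Of 10000 such draws 860 had at least 8, so this count is not unusual. The near-identical tef101, tef102 and tef103 had equal scores within each list, as had eft201 and eft202, so these copies are not separate observations. Among 11 plasma membrane and cell wall genes 4 were occupied at the start in wild type and 3 in abp1Δ, and 7 in the body in each. Of these 7, 6 had more covered bp in abp1Δ and 1, the glucose transporter gene ght5, had fewer, with 736 in wild type and 678 in abp1Δ. Among 10000 random draws of 7 genes with an interval, 952 had at least 6 with more, so this count is not unusual either. The glucanosyltransferase gene gas2 had 138 and 1044, and pma1 had 4408 and 4433. Of 16 chaperone and heat shock genes 4 and 3 were occupied at the start and 9 in the body in each list, with the most covered bp at hsp90, bip1 and ssa2, 2558, 2387 and 2204 in wild type and 2352, 2258 and 2140 in abp1Δ. None of 10000 random lists matched on gene length had as many occupied gene bodies as any of these 4 lists, in either genotype.

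Most histone genes had less covered length in the mutant list, some by a wide margin. Start windows were occupied in 9 of 10 histone genes in wild type and 7 in abp1Δ, and gene bodies in 9 in each list. Of the 9 genes, 8 had fewer covered bp in abp1Δ: hhf1 had 611 bp in wild type and 71 in abp1Δ, hht1 656 and 198, hhf2 409 and 223, hta2 740 and 537, hht3 527 and 404, and hhf3 158 and 70. For hta1, with 731 and 705, and htb1, with 1263 and 1261, the lists were nearly level. The H3 gene hht2 went the other way, with 654 and 699 bp. Over the 9 genes the covered length was 5749 bp in wild type and 4168 bp in abp1Δ, on average 71.4% and 49.9% of each gene. Of these genes 8 lie in 4 adjacent pairs, so they are not independent. Comparing covered length was chosen after the data were seen, for these and the other lists.

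Start windows of ribosomal protein genes were occupied in 55 of 138 in wild type and 60 in abp1Δ, with 47 in both, 8 in wild type alone and 13 in abp1Δ alone. This excess in abp1Δ depends on the window: with 500 bp each side, and in the body, 7 were in wild type alone and 3 in abp1Δ alone. It also depends on the stretch of chromosome III described below, which holds 4 of the 13. Outside that stretch 8 were in wild type alone and 9 in abp1Δ alone. In the body 114 and 110 were occupied, and of the 117 with an interval in either list 55 had more covered bp in abp1Δ and 60 in wild type. Of the 16 core stress response genes 1 was occupied at the start in wild type and 2 in abp1Δ, the difference being tpx1. Gene bodies were occupied in both lists for 3 of them, tpx1, sod1 and gpd1, which had 33, 673 and 1317 covered bp in wild type and 561, 734 and 1505 in abp1Δ.

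Several smaller lists had few intervals or none. None of 15 meiotic genes, 9 auxotrophy marker genes, 12 RNA polymerase II subunit genes or 16 wtf genes had one in the start window or the body in either list. Random lists had means of 0.93, 0.49, 1.07 and 1.02 occupied bodies in wild type, and for each list at least 3268 of 10000 had none, so these absences are not unusual. Among 22 mating and sexual differentiation genes the transcription factor gene esc1 was occupied at the start in wild type alone, with 1148 covered bp in the body in wild type and 22 in abp1Δ, and isp6 had body intervals in abp1Δ alone. Of 12 iron genes str2 and isu1 had body intervals in both lists, as had pho84 among 7 phosphate genes. The interval of str2 is that of rpl6, which lies inside it. Within 100 kb of the ends of chromosomes I and II, 7 of 124 genes had body intervals in wild type and 3 in abp1Δ. Random lists had means of 11.7 and 11.2, and 856 and 22 of 10000 had as few. The 4 genes in wild type alone there were the SPBPB10D8 transporter genes, whose shared sequence makes them 1 observation.

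**Figure D2:**
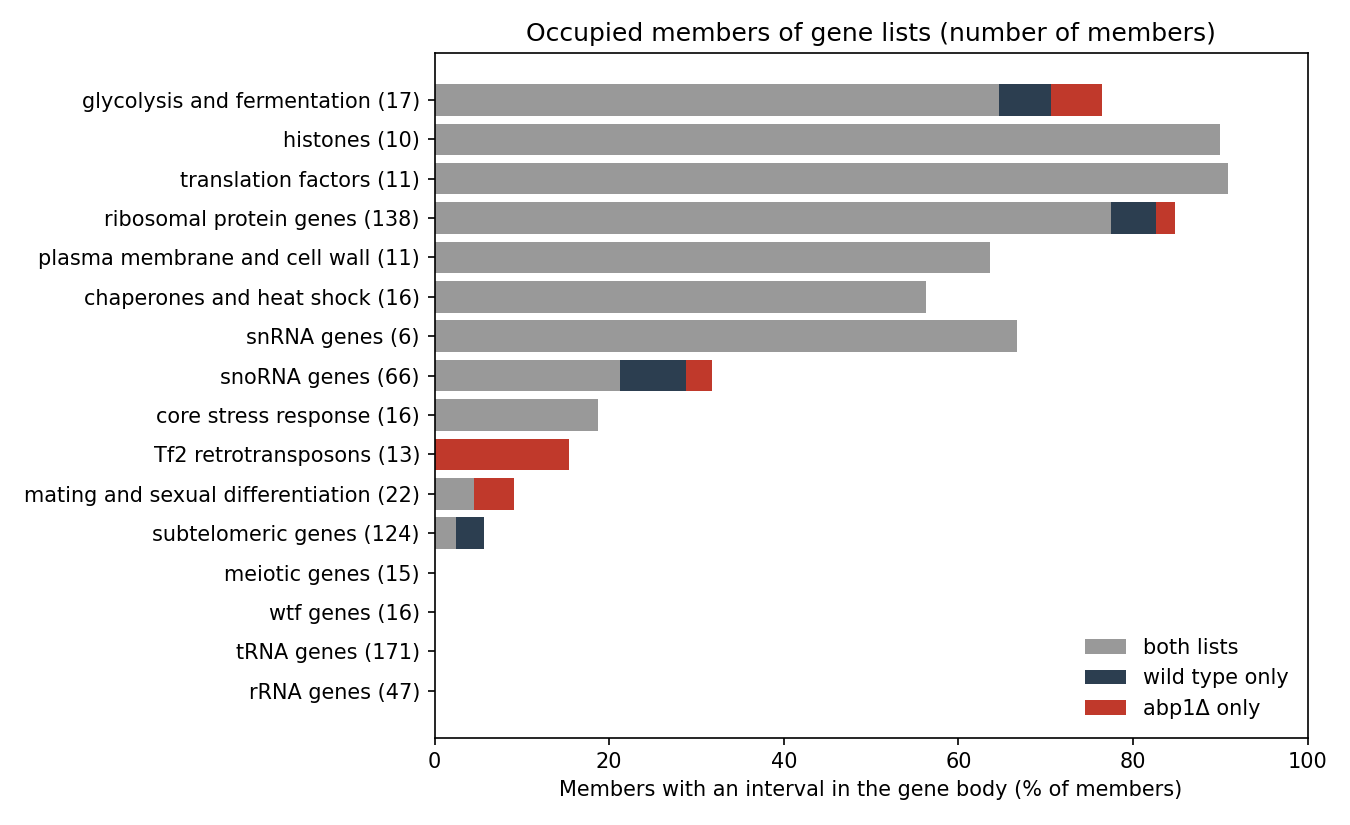
Percent of the members of each gene list with an interval between gene start and gene end, in both lists (grey), in wild type alone (dark blue) and in abp1Δ alone (red), with the number of members in brackets. Most occupied members are shared, while the 2 occupied Tf2 elements of 13 are limited to abp1Δ.

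Some non-coding RNA genes transcribed by RNA polymerase II also had intervals. Of 6 snRNA genes 5 were occupied at the start in both lists, among them snu2, snu5 and snu1, each covered over its whole length. Of 66 snoRNA genes 24 were occupied at the start in wild type and 23 in abp1Δ, with 20 in both, and 19 and 16 in the body, with 14 in both. Those in 1 list alone included sno12 and sno16 in wild type, with scores of 262 and 221, and snR88 and snR191 in abp1Δ, with 501 and 223. The window is wider than these genes: inside snR88 the score was 230, and snR191 had no interval inside it. Some genes occupied at the start in both lists, such as sno52, snoR39a and the snRNA gene snR48, had none inside them either. Among the 7171 other non-coding RNA genes, start windows were occupied in 269 in wild type and 265 in abp1Δ, with 216 in both. For the 7133 long non-coding RNA genes among them the shares were 3.76% and 3.72%, close to the 3.52% and 3.45% of all annotated genes. Since 89.6% and 90.4% of covered bases lay in protein-coding genes, intervals at any of these non-coding RNA genes may belong to an overlapping or neighbouring protein-coding gene. None of the 171 tRNA genes, which RNA polymerase III transcribes, had an interval in its start window or body.

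The series names the Tf2 retrotransposons and the ribosomal RNA genes, so each element was examined over its whole length. No Tf2 element had an interval in wild type. In abp1Δ 2 of 13 did, both on the plus strand of chromosome II: Tf2-10 (1965390 to 1969390) with 1004 covered bp and Tf2-11 (4414657 to 4418658) with 981, or 25.1% and 24.5% of the element. The highest score was 393 in both. The intervals began 692 bp from the start of each element and ended at 3415 bp in Tf2-10 and 3416 bp in Tf2-11. The elements are nearly identical to each other: 50-mers found once in the genome make up 4.10% of Tf2-10, 9.06% of Tf2-11 and at most 1.45% of any other element. Reads from any Tf2 element could therefore be placed at several, and how the aligner treated such reads is not given in the sources used here. When an element had to be covered over at least 50% of its length, none of the 13 counted.

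**Figure D3:**
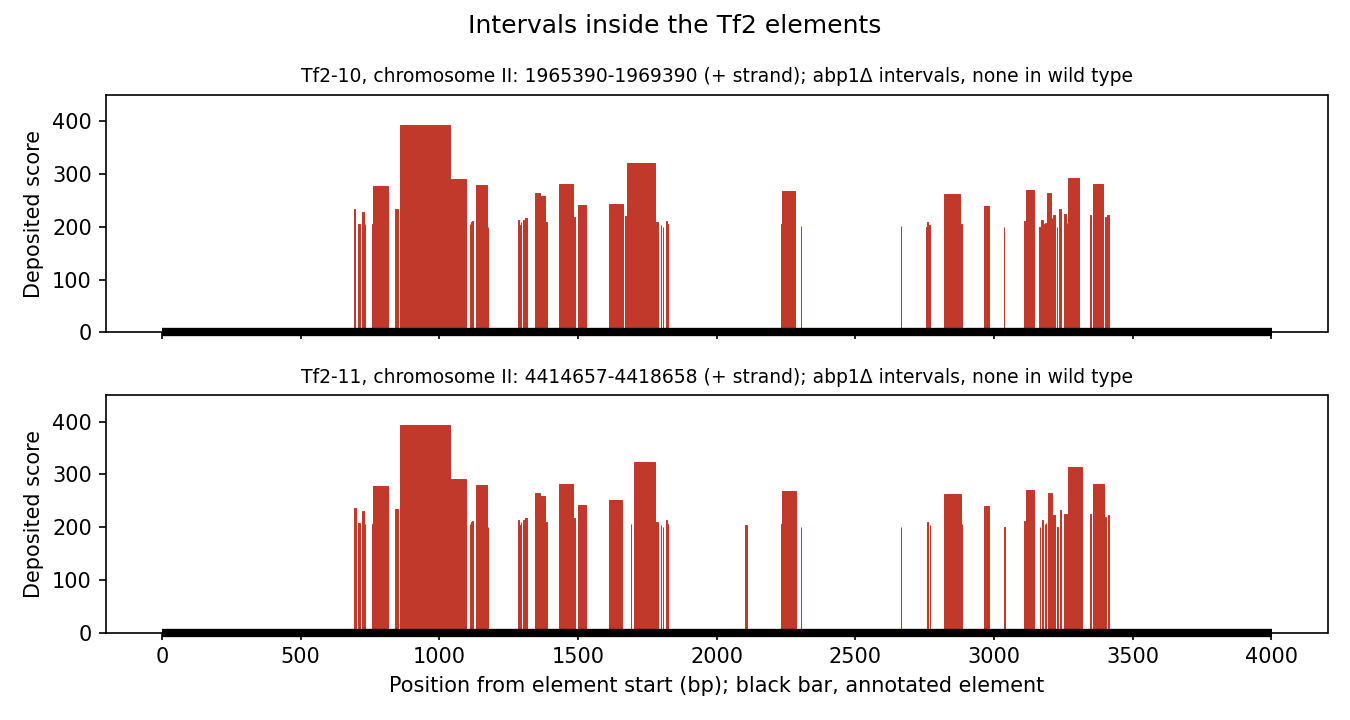
Deposited score of each abp1Δ interval inside Tf2-10 (top) and Tf2-11 (bottom), drawn against its position in bp from the start of the element, with the element as a black bar. The intervals occupy almost the same places in both copies, between 692 bp and 3416 bp, and reach a score of 393 in each.

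Around the Tf2 elements, 1 of 24 nearest protein-coding neighbours was occupied at the start in each list, knh4 beside Tf2-10, with a score of 834 in wild type and 1093 in abp1Δ. In the body the counts were 1 in wild type and 2 in abp1Δ, the second being the adducin gene SPBC1289.14 beside Tf2-11 (4412241 to 4413599), with 738 covered bp in abp1Δ alone. None of the 238 annotated long terminal repeats overlapped an interval, and with 500 bp added on each side 5 did in wild type and 8 in abp1Δ. No interval lay over any of the 11 annotated 18S, 5.8S and 28S ribosomal RNA genes or the 36 genes for 5S ribosomal RNA in either list. Around 2 of the 5S genes an interval fell inside the start window in wild type, beside SPRRNA.37 and SPRRNA.26. The 18S, 5.8S and 28S genes hold no 50-mer found once in the genome, so an absence there can come from the handling of repeated reads as well as from low signal.

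Chromosome III differed most between the lists, as its covered length showed, and a stretch of it was singled out after the values were seen. From rpl3601 to rpl1201 (506350 to 691646, or 185.3 kb) 15 of 75 protein-coding genes had an interval in either list, and all 15 had more covered bp in abp1Δ. Outside it 209 genes had more in abp1Δ and 179 more in wild type. On chromosome III outside the stretch 33 genes had more in abp1Δ and 27 more in wild type. Their gene bodies had 32085 covered bp in wild type and 38426 in abp1Δ, so the stretch does not hold all of the chromosome's gain. Within the stretch rpl3601 had 35 covered bp in wild type and 350 in abp1Δ, rps1201 62 and 432, rpl2802 301 and 578, and sap1, which encodes a DNA-binding protein of mating-type switching, 1075 and 1750. The genes scw1, sts5, msy1 and bpb1 had intervals in abp1Δ alone. Some of these genes overlap each other, such as sap1 and SPCC1672.01, and share their intervals. Over the 15 genes 6382 bp were covered in wild type and 12319 bp in abp1Δ, on average 28.5% and 57.9% of each gene. The 7 ribosomal protein genes of the stretch were covered over 38.0% and 78.7% on average, while the 110 others with an interval were covered over 45.3% and 42.1%. The snoRNA gene sno12, at 583416 to 583605, lies inside the stretch and had 124 covered bp in wild type and none in abp1Δ. Of the 27 genes occupied at the start in abp1Δ alone 6 lay in this stretch, and without it the count was 21, against 30 in wild type alone.

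**Figure D4:**
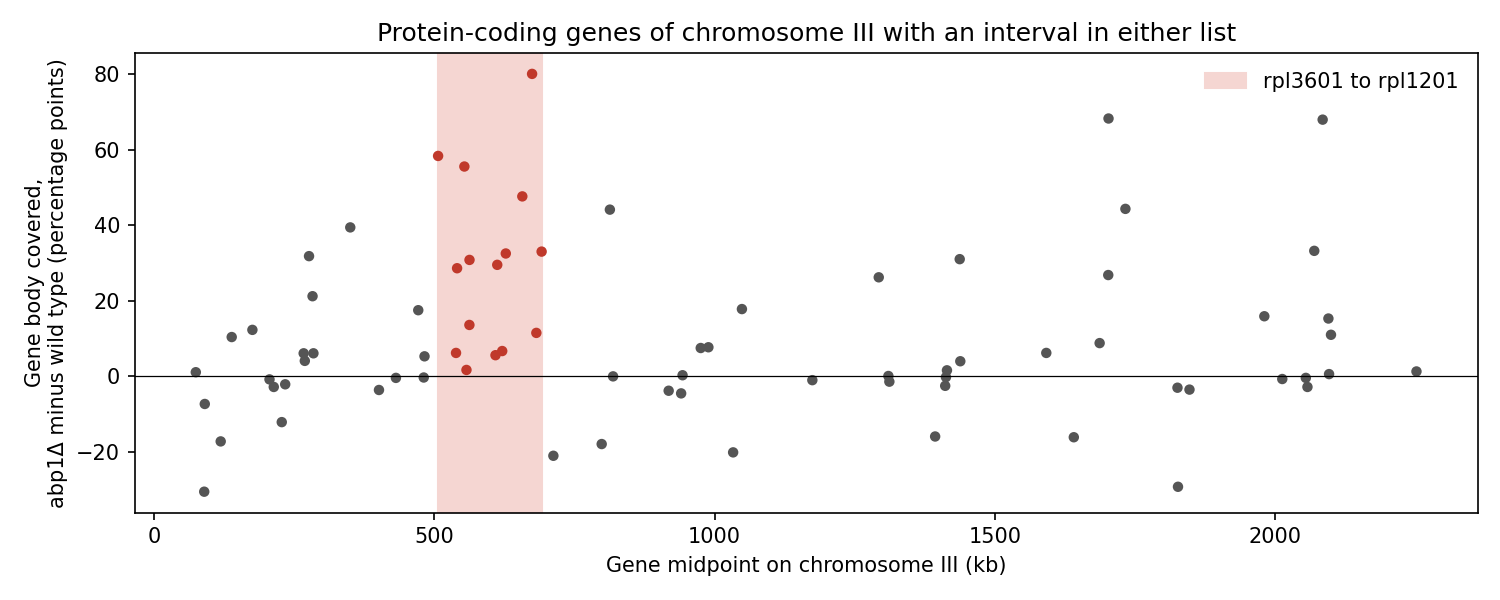
Percent of the gene body covered in abp1Δ minus that in wild type, in percentage points, for each protein-coding gene of chromosome III with an interval in either list, against the gene's midpoint in kb. The 15 genes from rpl3601 to rpl1201 (red points, shaded stretch) all lie above 0, while genes on both sides (grey) lie above and below it.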

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

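No paired analysis was possible because each genotype has 1 list and no test was made. Some orders changed: gene bodies took more intervals than start windows in the main counts and fewer with a window of 500 bp. More genes were in wild type alone than in abp1Δ alone in the main counts, 30 against 27, but 28 against 29 with the upper 50% by score and 24 against 26 with single-copy genes alone. Listed genes went from 91 against 92 to 158 against 150 with 500 bp. Of the main values under each alternative, 73 stayed within their counting interval or within 1.5 times the count, and 56 moved. Of the values for single gene lists and minor classes, 348 stayed and 74 moved. Each cause below lies in how the alternative is built, such as fewer intervals or wider windows, and no other cause was tested. Merging gaps for overlap and classes, classing against protein-coding genes alone, single-copy genes alone and leaving out the chromosome III stretch were chosen after seeing the data. These last 2 moved no count beyond the limits just given. Without the stretch, though, the genes in abp1Δ alone fell from 27 to 21, against 30 in wild type alone. Values are given for wild type and then abp1Δ. With the upper 50% of each list by score, the lists held 1621 and 1425 intervals of median width 24 and 25 bp, and 63.2% and 49.96% were shared. With gaps up to 100 bp merged, there were 477 and 442 regions of median width 346 and 388 bp, 73.0% and 73.3% were shared, start windows took 30.6% and 27.8%, and gene bodies 67.3% and 70.6%. A reciprocal overlap of 50% left 8.02% and 9.12% shared, and a gap of up to 250 bp gave 82.6% and 75.4%. With a start window of 100 bp, 66 and 65 protein-coding genes were occupied, 52 in both, 14 in wild type alone and 13 in abp1Δ alone. With 500 bp the counts were 313 and 291, with 263 in both, 50 in wild type alone and 28 in abp1Δ alone. Start windows then took 66.0% and 64.2% of intervals and gene bodies 33.4% and 34.9%. Over the gene body 367 and 364 genes were occupied, 319 in both, 48 in wild type alone and 45 in abp1Δ alone. With no interval of the other list within 1 kb, 7 genes were in wild type alone and 4 in abp1Δ alone. Against protein-coding genes alone, start windows took 12% and 10.2% and gene bodies 77.1% and 80.5%. Of 315 genes on the expression, stress and repeat lists, 91 and 92 were occupied at the start, 13 in wild type alone and 14 in abp1Δ alone. With 500 bp these were 158 and 150 with 13 in wild type alone and 5 in abp1Δ alone, in the body 168 and 165 with 8 and 5 in 1 list alone, and with the 1 kb guard 0 and 1 in 1 list alone. With 500 bp added on each side, 3 and 2 of the 5S rRNA genes had an interval, and with 50% of the element required 0 Tf2 elements had one in abp1Δ. Classing by summit was not run. Depth is unknown, so a gene absent from a list may lie just under a score of 200.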

Other observations

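All tests in this part were chosen only after the result was seen. Some genes tied to nutrient supply had intervals in 1 list alone. Of 10 sulfur assimilation genes 4 had body intervals in wild type and 1 in abp1Δ. The sulfate transporter gene sul1, the sulfite reductase gene sir1 and met17 had 215, 90 and 114 covered bp in wild type and none in abp1Δ, while sua1 had 638 and 605. Of 10 nitrogen and vacuolar protease genes none had a body interval in wild type and 3 in abp1Δ, namely isp6, cpy1 and amt1. These 2 lists were drawn up around genes already seen to differ, so they cannot show whether these groups differ. In SPAC27D7.09c and SPAC27D7.11c, nearby genes on chromosome I, 253 and 1125 bp were covered in abp1Δ and none in wild type. Of their 50-mers 70.3% and 21.1% occur more than once in the genome, so the 2 genes may share reads and need not be separate observations.

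The nutrient genes in 1 list alone raise the question of values near the lowest score of 200. The cpy1 region, with a score of 1828, ranked 9 of 442 in the abp1Δ list and the 8 ranked above it all met a wild-type interval, which argues against values near the threshold of 200 for this gene. The lower score of isp6 and amt1 was 317 and the highest of sul1, sir1 and met17 was 274, and since these genes were picked for their intervals and the scaling of the lists is unknown, that explanation stays open for these 5. Another growth state of the abp1Δ culture is a candidate explanation that cannot be told apart from the deletion itself, because there was 1 ChIP library for that genotype. An effect of losing Abp1 stays open and untested.

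The gain along chromosome III from rpl3601 to rpl1201 had the highest mean of all runs of 15 consecutive genes with intervals, 29.4 percentage points of gene body covered. Of 10000 shuffles of the gene order 0 reached it, which argues against chance order of genes. Shuffles treat genes as independent, but this run holds genes that share intervals and the near-identical rpl1202 and rpl1201, so they can understate chance. With 1 gene kept of each overlapping group, the highest run of 15, from rpl1702 to rpl1201, had a mean of 28.9 points. Of 1000 shuffles 1 reached that mean. The run length was set to the number of genes in the stretch after it was seen, 1 of 1000 shuffles in a separate draw and 5 of 1000 with runs of 10 genes reached the mean, and the run with the largest loss, from SPBPB10D8.04c to rps27 on chromosome II at -21.3 points, was matched by 59 of 10000 shuffles but opens with 4 copies that count as 1 observation. Reads shared between near-identical genes are argued against for the 12 single-copy genes of the stretch, which hold few repeated 50-mers. All of the 12 had more covered bp in abp1Δ, but the stretch was picked for its gain, so this count adds no support. They are also not all separate: sap1 and SPCC1672.01 share intervals, and rpl35A01 lies in 1 region with eft202, of whose 50-mers 84.4% are repeated. For the other genes of the stretch shared reads stay possible. A doubled copy number of the segment in the abp1Δ culture may account for the gain. Its 8 regions found in both lists, with scores of 223 to 583 in wild type and 373 to 1016 in abp1Δ, all ranked higher in abp1Δ. Their median rank was 58 in abp1Δ against 175 in wild type among the same 309 regions. Outside the segment 130 of 301 regions ranked higher in abp1Δ. The 8 regions are not independent, since those of rpl1202 and rpl1201 share sequence and have equal scores. The region of eft202 has the same scores as its near-copy eft201 outside the segment. The highest score of the segment's abp1Δ-only regions, 329, stays below the 400 that doubling a value under 200 allows if the lists share a scale. Only 5 of the 118 abp1Δ-only regions of the whole list reached 400, so this value cannot tell extra copies from none. The stretch was picked for its gain, the scaling is unknown, 1 of 21 regions, at sno12, was covered in wild type alone, and input coverage was not analysed here, so extra copies cannot be told apart from local regulation or from an effect of the deletion.

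The intervals at Tf2-10 and Tf2-11 were weighed in the same way. Shared reads placed at every copy would mark all 13 elements, and 2 were marked. Each tied read placed at 1 copy would give each element its own pattern, yet 81.5% of the Tf2-10 intervals recurred at Tf2-11 within 2 bp and with the same score. Reads that match only these elements could seed the signal, since these elements hold the most sequence found once in the genome. Of the covered bases 36.4% lie more than 400 bp, the upper end of the sheared fragments, from such sequence. Sequence found in these 2 elements and nowhere else was not counted with it, so this share does not count against the explanation. That explanation cannot be told apart from other rules for repeated reads that the sources used here do not give. A change in Ser5P occupancy of Tf2 elements without Abp1 stays open and untested.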
